A study of Homo sapiens with 28 samples.

How the data were processed

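RNA from 7 AML cell lines, treated for 96 hours with 1 µM GSK3484862 or 0.1% DMSO, was hybridised to 28 Affymetrix Human Genome U133 Plus 2.0 arrays. Cell line, treatment and replicate number were taken from the sample labels. The authors deposited 1 table of log2 values with 27306 probe sets and 1 column per array. Background correction, summarisation, normalization between arrays and any filter on probe sets are not given in the sources used here. Per the submitters' processing notes limma was used, with no version or role. The values themselves showed a log2 scale, a lowest value of 2.1 that occurred in all arrays, and array medians between 8.33 and 8.51, so they were taken as already normalized and used as they stood. Between 288 and 691 probe sets per array (1.05% to 2.53%) lay at the floor, where values have no order. No scan dates or hybridisation batches were used here, so a batch shared by arrays of 1 group could not be tested. All per-sample columns were used.

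Gene names came from the platform annotation paired with the probe sets, which can be old. Of the probe sets, 22580 had 1 gene symbol, 1098 had several and 3628 had none listed. Of those with 1 symbol, 22567 matched the gene table by gene identifier, and 0 symbols changed. Probe sets with several symbols or none were left out of the main tests. Each gene was represented by its probe set with the highest mean over all 28 arrays, a choice blind to treatment, which left 11676 genes, 6051 of them with more than 1 probe set. For named genes the other probe sets were checked, and those that moved in the opposite direction are given beside the value. Table rows that start with AFFX numbered 0. No genomic coordinates were used.

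Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior) in 1 fit of 14 groups, line by treatment, so that all lines shared 1 estimate of the spread between duplicates (14 residual and 2.28 prior degrees of freedom). The contrasts were GSK3484862 minus DMSO in each line, the mean of the 7 within-line changes, and a moderated F-test of the 6 independent differences between lines. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. The p-value of the average contrast concerns these 7 lines, since its error is the spread between duplicates. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 26 lists for the average and over 182 tests of a list in a line, and repeated with an estimated correlation and with fry. Sharing of calls was set against n1 × n2 / N, and against independent calls for the number of lines, with no p-value across genes. Relations across the 7 lines were given with Pearson's r and Spearman's rho and exact two-sided permutation p-values over all orders of the lines.

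The groups, tests, gene lists, naming rule and alternatives were fixed before the data were examined. The rule named, for the average, the 12 largest rises and 8 largest falls among called genes with the same sign in all 7 lines, for each line the 3 largest rises and 2 largest falls among called genes with both treated arrays on 1 side of both DMSO arrays, the 6 genes with the smallest F-test p, and up to 4 called members of each list with the largest average change. DNMT1, DNMT3A, DNMT3B and UHRF1 were always given. XIST, Y-linked genes and probe sets with no or several symbols were left out of naming, and genes named outside the rule are marked. The 26 lists were DNA methylation machinery, cancer-testis antigens, germ-cell genes, interferon response genes, nucleic acid sensing, MHC class I, MHC class II, monocyte, neutrophil, basophil, erythroid and megakaryocyte markers, stem and HOX genes, lymphocyte markers, epithelial genes, imprinted genes, tumour suppressors, S-phase genes, G2 and mitosis genes, ribosome biogenesis and MYC targets, p53 targets, BCL2 family, cholesterol synthesis, unfolded protein response, cytokines and reference genes.

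The alternatives were quantile normalization, centring of each array on its median, a filter that kept genes with at least 1 group mean above the median of all values (8.43), the mean of all probe sets per gene, leaving out probe sets marked as prone to cross-hybridise, trend and robust options of eBayes, array weights, the replicate number as a block, each line fitted on its own 4 arrays, lines as units, each line, array or replicate left out, a limit of 2-fold, and an adjusted p under 0.01. Offsets before a log transform did not apply to log2 values. A fit without SKM1 for the results of single lines and the test of each line against the mean of the other 6 were added after the data were seen. The fits were tested on simulated data with the real genes and line means and, for each gene, 1 spread shared by all lines. Of 50 genes changed by 0.5 in all lines 94% were recovered on average, and of 50 changed by 1 all 50. Of 50 genes changed by 0.5 in GDM1 alone 42% were recovered there, and of 50 changed by 1 82%, with 14% and 58% recovered by the F-test of differences. False calls made up 3.45% of the calls on average and 6.87% of those in GDM1, and in SHI1 8.96% (6 of 67), over 11676 genes. All 11 lists shifted by 0.3 were recovered and 0 of 13 others were called. The simulated noise was independent between genes, so this could not test the preset correlation of 0.01. It also had no floor and the same spread in every line. In the real data the SD of a single array, pooled over treatments, ran from 0.169 in SHI1 to 0.297 in SKM1. The simulated rates therefore do not test the shared estimate of spread behind the counts per line. With labels exchanged within the lines of the real arrays a median of 6 lists was called. Such splits could keep the real or the fully exchanged labels in single lines, so this is not a rate of false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.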

Results

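Gene expression was measured on Affymetrix Human Genome U133 Plus 2.0 arrays in 7 established acute myeloid leukaemia (AML) cell lines, GDM1, MOLM13, SKM1, THP1, SKNO1, NOMO1 and SHI1. Each line was grown for 96 hours (4 days) with 1 µM GSK3484862, an inhibitor of the maintenance DNA methyltransferase DNMT1, or with 0.1% DMSO as vehicle. The series design gives biological duplicates, so each of the 14 groups held 2 arrays and the series 28. The values were log2 probe set signals between 2.1, a floor shared by all arrays, and 17, with array medians from 8.33 to 8.51. Within groups the duplicates correlated at r = 0.990 to 0.998 across genes, which are not independent replicates, and the SD of a single array ran from 0.161 to 0.305, widest in treated SKM1. The number of arrays limits the precision. Unless another error is named, changes are log2 GSK3484862 minus DMSO with the standard error of the limma fit, and where the DMSO signal lay near the floor the size of a rise was limited by that floor.

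The first comparison asked which genes the inhibitor changed on average over the 7 lines. The genes given first are those whose change had the same sign in all 7 lines, a sign that carries no information where both signals lay at the floor. By such values COL14A1 (0.00 in SHI1) and LGALS3BP (0.01 in MOLM13) were kept among them, and ZNF595, which had the largest average (5.54 ± 0.11), was not (-0.01 in GDM1). MAGEB2, a cancer-testis antigen, rose by 3.81 ± 0.08 (adjusted p = 1.61e-15) and was called up in 6 lines. NFE4, a regulator of fetal globin genes, rose by 2.82 ± 0.07 and was called up in all 7 lines, from 0.83 in SHI1 to 5.85 in SKM1. MMP9, a matrix metalloproteinase of neutrophil granules, was the other gene called up in all 7 lines and rose by 1.18 ± 0.09. The falls were smaller, led by MANEAL at -1.67 ± 0.14.

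The other large rises among these genes were DCAF4L1 (3.56 ± 0.20), the collagen gene COL14A1 (2.92 ± 0.13), the calcium-binding protein gene S100P (2.42 ± 0.11), SERPINF1 (2.31 ± 0.14), the matrix protein gene TGFBI (2.28 ± 0.21), the eosinophil granule gene PRG2 (2.21 ± 0.16) and LGALS3BP (2.19 ± 0.17). The adenosine receptor gene ADORA3 rose by 2.14 ± 0.13, the antitrypsin gene SERPINA1 by 2.00 ± 0.09 and ANPEP, which encodes the myeloid surface aminopeptidase CD13, by 1.99 ± 0.10. COL14A1 and TGFBI were called up in 3 lines each, LGALS3BP in 4, S100P and ADORA3 in 6. Without MOLM13 S100P was at 1.61 and ANPEP at 1.24. The falls after MANEAL were the mitochondrial adenylate kinase gene AK4 (-1.31 ± 0.13), the tyrosine kinase gene MATK (-1.07 ± 0.06), PALS2 (-1.0 ± 0.07), CDK5R1 (-0.97 ± 0.08), IQCK (-0.92 ± 0.10), the divergent transcript RNASEH1-DT (-0.89 ± 0.05) and the ciliary gene RPGRIP1L (-0.87 ± 0.16). MATK and RNASEH1-DT were called down in all 7 lines.

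By this test 6039 of 11676 genes (51.7%) passed an adjusted p of 0.05, 2704 up and 3335 down. At 2-fold or more the balance turned, with 161 rises and 6 falls. Of the genes called, 1902 had the same sign in all 7 lines, 700 up and 1202 down, signs at the floor included. The median change over all genes was -0.02. Taken with the 7 lines as the units, so that the spread between lines sets the error, 825 genes passed, 296 up and 529 down. Of the 20 genes above with 1 sign in every line, 12 passed that test too, namely MAGEB2, DCAF4L1, NFE4, ADORA3 and all 8 falls. These 20 were picked from the same values for that 1 sign, which favours passing a test of consistency between lines. Of the 119 named genes that passed on average, 31 passed with lines as the units. Most of the 119 lost their call by it, for example S100A8 (adjusted p = 0.248), IFI44L (adjusted p = 0.240) and HDC (adjusted p = 0.204). With 1 replicate of every group left out and line as a block, limma called 0 genes without replicate 1 and 0 without replicate 2, where 2954 and 3171 had an unadjusted p under 0.05.

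The target itself changed little at the RNA level. The DNMT1 signal moved by -0.09 ± 0.03 (adjusted p = 0.00700), from -0.48 in GDM1 to 0.09 in NOMO1, and without GDM1 it did not pass (-0.03, adjusted p = 0.448). UHRF1, the partner that brings DNMT1 to newly replicated DNA, fell by 0.10 ± 0.03 on average, but its change was 0.03 without GDM1. The de novo methyltransferase genes did not pass, with -0.06 ± 0.04 for DNMT3A (adjusted p = 0.255, 1 of its 2 probe sets with that sign) and 0.06 ± 0.04 for DNMT3B (adjusted p = 0.163). Of 15 measured DNA methylation machinery genes 2 rose and 8 fell, and the list was not called by camera (mean -0.07, adjusted p = 0.186) but was called down by fry (adjusted p = 1.37e-04). Its mean was -0.32 in GDM1 and -0.03 without GDM1. In GDM1 alone camera called it down (adjusted p = 0.0328), a call lost with an estimated correlation (adjusted p = 0.188). MBD3, a methyl-CpG-binding-domain protein gene, fell by 0.30 ± 0.04, HELLS by 0.25 ± 0.09 and ZBTB33 by 0.17 ± 0.03. HELLS lost its call without GDM1 (-0.05, adjusted p = 0.597) or MOLM13 (-0.24, adjusted p = 0.0581), and ZBTB33 without MOLM13 (-0.09, adjusted p = 0.0774). TET2, a methylcytosine dioxygenase gene, rose by 0.28 ± 0.04 on its brightest probe set, but only 1 of its 3 probe sets had that sign and the mean of the 3 did not pass (0.07, adjusted p = 0.305).

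Next, 26 gene lists were tested with camera. Of 6 measured cancer-testis antigens 4 rose and 0 fell (mean 1.68, adjusted p = 1.95e-05). Besides MAGEB2 these were MAGEA4 (3.17 ± 0.12, called up in 4 lines), TKTL1 (2.17 ± 0.12, called up in 3) and PRAME (0.85 ± 0.05, called up in 5). Of 7 germ-cell, meiosis and piRNA-pathway genes 5 rose and 1 fell (mean 0.69, adjusted p = 0.00909), with 5 up and 2 down when adjusted over the list alone. GTSF1, a piRNA-pathway gene, rose by 2.29 ± 0.04, TDRD9 by 1.30 ± 0.19, the meiotic gene HORMAD1 by 0.91 ± 0.10 and PIWIL4 by 0.81 ± 0.08. HORMAD1 rested on SKM1, without which it did not pass (0.18, adjusted p = 0.159). Without MOLM13 GTSF1 was at 1.26, and without SKM1 at 1.37. Outside MOLM13 and SKM1 the DMSO arrays of GTSF1 already lay at 12.7 or more. The germ-cell list had a mean of 0.46 without SKM1, 0.00 in SKNO1 and 0.06 in SHI1, and its call was lost with lines as the units (adjusted p = 0.120). Both lists covered a small part of what was fixed, 6 of 50 and 7 of 43 genes, the others being not analysed here. As any filter on probe sets before deposit is not given, it is not known whether these members were kept for their signal in some arrays. Other lists were also covered in part, such as the erythroid (4 of 27), megakaryocyte (8 of 24), lymphocyte (11 of 39) and epithelial lists (12 of 37).

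Antiviral and antigen presentation genes rose as well. Of 46 type I interferon response genes 39 rose and 1 fell (mean 0.64, adjusted p = 7.29e-15), and 40 rose when adjusted over the list alone. The size of that mean rested on GDM1 in large part, as it was 0.39 without GDM1, and the list was not called in SKNO1, NOMO1 or SHI1. LGALS3BP led, called up in GDM1, SKM1, THP1 and SKNO1 only, followed by IFI44L (1.57 ± 0.18, but 0.81 without GDM1), EPSTI1 (1.41 ± 0.12, but 0.67 without GDM1) and IFIT1 (1.32 ± 0.20). Among nucleic acid sensing genes 6 of 13 rose and 1 fell (mean 0.25, adjusted p = 0.0133), a call that was lost with the list's own correlation, adjusted p = 0.0604 with an estimated correlation. SAMHD1, a dNTP hydrolase that restricts viruses, rose by 1.21 ± 0.06, the RNA sensor gene TLR8 by 0.73 ± 0.11, IFI16 by 0.56 ± 0.13 and IFIH1 by 0.33 ± 0.05 (1 of its 2 probe sets with that sign). Without GDM1 SAMHD1 was at 0.45 and IFIH1 at 0.16, and IFI16 was at 0.24 without SKM1. TLR8 did not pass without MOLM13 (0.21, adjusted p = 0.174), nor the list without GDM1 (mean 0.18, adjusted p = 0.0779). Of 20 MHC class I and antigen processing genes 11 rose and 0 fell (mean 0.23, adjusted p = 3.27e-05). The class I activator gene NLRC5 rose by 0.98 ± 0.07, HLA-E by 0.60 ± 0.03, HLA-B by 0.40 ± 0.05 and HLA-C by 0.39 ± 0.04, where NLRC5 was at 0.63 and HLA-B at 0.24 without GDM1. MHC class II genes gave 6 rises and 1 fall of 14 (mean 0.32, adjusted p = 0.0230, but adjusted p = 0.343 with an estimated correlation), led by HLA-DMA (0.89 ± 0.20), HLA-DRA (0.64 ± 0.20), CD74 (0.56 ± 0.12) and CTSS (0.45 ± 0.03). Without SKM1 that list did not pass (mean 0.12, adjusted p = 0.130), HLA-DMA was at 0.50, and HLA-DRA did not pass without SKM1 (0.37, adjusted p = 0.0704) or MOLM13 (0.34, adjusted p = 0.252).

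Markers of mature blood cells rose in several lineages. Of 29 monocyte and macrophage markers 21 rose and 1 fell (mean 0.55, adjusted p = 5.99e-06), and 22 rose when adjusted over the list alone. S100A8 and S100A9, the subunits of calprotectin, rose by 2.05 ± 0.15 and 1.94 ± 0.19, the endotoxin co-receptor gene CD14 by 1.34 ± 0.16 and the integrin gene ITGAM by 1.03 ± 0.18. S100A8 was at 1.01 without GDM1, S100A9 at 1.05 without MOLM13 and CD14 at 0.83 without SKM1. Of 20 neutrophil granule genes 15 rose and 0 fell (mean 0.57, adjusted p = 5.99e-06), among them CEACAM6 (1.2 ± 0.17), FPR1 (1.19 ± 0.09) and the granulocyte transcription factor gene CEBPE (1.18 ± 0.08). Without SKM1 CEACAM6 was at 0.63 and FPR1 at 0.66, and without MOLM13 CEBPE was at 0.77. Basophil, mast cell and eosinophil markers gave 7 rises and 1 fall of 12 (mean 0.81, adjusted p = 1.29e-04), with PRG2, the histidine decarboxylase gene HDC (1.75 ± 0.10), CLC (1.71 ± 0.12) and PRG3 (1.46 ± 0.19), of which HDC was at 0.78 without SKM1 and CLC at 1.08 without MOLM13. Megakaryocyte and platelet markers gave 5 rises and 1 fall of 8 (mean 0.40, adjusted p = 0.0128, but adjusted p = 0.0776 with an estimated correlation), led by PPBP (0.98 ± 0.07), RAB27B (0.89 ± 0.09), ITGA2B (0.75 ± 0.17) and NFE2 (0.41 ± 0.07). PPBP was at 0.24 without GDM1, which ended its lead, RAB27B at 0.48 without SKNO1, and NFE2 at 0.25 without MOLM13 and 0.27 without THP1.

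Cytokine and chemokine genes gave 14 rises and 1 fall of 24 (mean 0.43, adjusted p = 2.74e-05), with IL32 at 1.66 ± 0.10, IL18 at 1.26 ± 0.14 (0.64 without SKNO1), TNF at 1.08 ± 0.18 and CXCL8 at 0.90 ± 0.12. Of 12 epithelial genes 6 rose and 0 fell (mean 0.37, adjusted p = 0.00746), and 8 rose and 1 fell when adjusted over the list alone. These included the keratin gene KRT18 (0.90 ± 0.15), the protease inhibitor genes SPINT2 (0.84 ± 0.11, but 0.46 without SHI1) and SPINT1 (0.79 ± 0.07), and JUP (0.73 ± 0.10). Of 22 tumour suppressor genes with promoter methylation described in leukaemia 13 rose and 2 fell (mean 0.17, adjusted p = 0.00561). DAPK1, a death-associated kinase gene, rose by 0.57 ± 0.06, PCDH17 by 0.53 ± 0.15 and the cyclin-dependent kinase inhibitor gene CDKN1C by 0.49 ± 0.16, while BNIP3 fell by 0.49 ± 0.13. DAPK1 was at 0.36 without MOLM13 and PCDH17 at 0.24 without SKM1. Calls were lost for CDKN1C without GDM1 (0.25, adjusted p = 0.305) or SHI1 (0.47, adjusted p = 0.0514), PCDH17 without SHI1 (0.38, adjusted p = 0.0684) and BNIP3 without MOLM13 (-0.36, adjusted p = 0.0506). BCL2 family and death receptor genes gave 13 rises and 5 falls of 23 (mean 0.14, adjusted p = 0.0312, but adjusted p = 0.162 with an estimated correlation), and without SKM1 the list did not pass (mean 0.11, adjusted p = 0.0993). Their largest change was in BCL2A1, which like BCL2 opposes apoptosis (1.27 ± 0.12), next to CASP10 (0.45 ± 0.08), APAF1 (0.37 ± 0.09) and BCL2 (-0.37 ± 0.04).

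The growth programmes moved the other way. Of 39 S-phase genes 35 fell and 0 rose (mean -0.28, adjusted p = 1.18e-13; mean -0.18 without GDM1), with GINS3 at -0.47 ± 0.07, the chromatin assembly gene CHAF1B at -0.47 ± 0.04, EXO1 at -0.47 ± 0.04 and the uracil glycosylase gene UNG at -0.45 ± 0.04. Of 32 ribosome biogenesis and MYC target genes 29 fell and 0 rose (mean -0.30, adjusted p = 5.08e-13). MYC fell by 0.49 ± 0.04 and was called down in 6 lines, CAD fell by 0.49 ± 0.04, PES1 by 0.44 ± 0.02 and GAR1 by 0.43 ± 0.03. Of 42 G2 and mitosis genes 20 fell and 1 rose (mean -0.08, adjusted p = 0.00612), but the call did not hold, adjusted p = 0.343 with an estimated correlation, and without GDM1 the mean was 0.03. In SKNO1 and NOMO1 camera called this list up (means 0.07 and 0.08, adjusted p = 0.0237 and 0.0144), calls that were also lost, adjusted p = 0.538 and 0.50 with an estimated correlation. Among them PLK1 fell by 0.27 ± 0.06, CCNA2 by 0.23 ± 0.03 and BIRC5 by 0.22 ± 0.03, and UBE2C rose by 0.34 ± 0.11. CCNA2 was at -0.12 and BIRC5 at -0.11 without GDM1. PLK1 did not pass without GDM1 (-0.13, adjusted p = 0.0873), nor UBE2C without SKM1 (0.15, adjusted p = 0.242).

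The other lists were not called by camera, although fry, which asks whether members moved at all and not whether they moved more than other genes, called 6 of these 9. Besides the methylation machinery these were the stem and HOX (up, adjusted p = 0.00321), lymphocyte (up, adjusted p = 0.0132), p53 (up, adjusted p = 6.47e-05), cholesterol (down, adjusted p = 0.0162) and reference lists (down, adjusted p = 5.05e-04). Of 27 p53 target genes 8 rose and 6 fell (mean 0.18, adjusted p = 0.137), with rises in TP53I3 (1.36 ± 0.11), TNFRSF10C (1.31 ± 0.17), TP53INP1 (1.03 ± 0.16) and ZMAT3 (0.59 ± 0.04). Of 19 stem, progenitor and HOX genes 7 rose and 4 fell (mean 0.04, adjusted p = 0.410), ADGRG1 and GATA2 up by 1.03 ± 0.11 and 0.51 ± 0.03, the receptor kinase genes FLT3 and KIT at -0.87 ± 0.09 and -0.49 ± 0.13, with FLT3 at -0.55 without SKM1. The mean of the stem and HOX list was 0.01 without SHI1 and 0.07 without NOMO1. Of 11 T, B and NK lymphocyte markers 4 rose and 2 fell (mean 0.11, adjusted p = 0.301), with CD3D at 0.75 ± 0.13, CD4 at 0.70 ± 0.16, PRF1 at 0.40 ± 0.05 and EBF1 at -0.43 ± 0.14, the last not passing without THP1 (-0.19, adjusted p = 0.333). CD3D was at 0.44 without SKM1, and PRF1 at 0.26 without NOMO1 and 0.15 without SHI1. The mean of the lymphocyte list was 0.05 without SKM1, 0.06 without SHI1 and 0.17 without THP1. Of 18 imprinted genes 5 rose and 2 fell (mean 0.08, adjusted p = 0.464), led by PAX8-AS1 (0.88 ± 0.10), L3MBTL1 (0.42 ± 0.13) and NAP1L5 (-0.41 ± 0.13), each of which lost its call without some line: PAX8-AS1 was at 0.28 without THP1, L3MBTL1 at 0.25 without GDM1, 0.36 without MOLM13 and 0.33 without THP1, and NAP1L5 at -0.29 without MOLM13 (-0.27 without SKM1). Of 19 cholesterol synthesis genes 1 rose and 9 fell (mean -0.11, adjusted p = 0.0848), TM7SF2 up by 0.62 ± 0.09, MVK at -0.43 ± 0.08, LSS at -0.31 ± 0.05 and DHCR7 at -0.31 ± 0.06.

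Of 29 unfolded protein and ATF4 response genes 9 rose and 9 fell (adjusted p = 0.674), with a mean of -0.01 (0.000923 after quantile normalization), a median of 0.01 and a test that ranked upward. ATF5 rose by 0.69 ± 0.08 and NUPR1 by 0.39 ± 0.06, while CHAC1 fell by 0.56 ± 0.10 and SLC7A5 by 0.38 ± 0.04. ATF5 was at 0.32 without SKM1, NUPR1 at 0.18 without MOLM13 and CHAC1 at -0.33 without GDM1. Of 4 erythroid markers 0 rose and 1 fell (mean -0.02, adjusted p = 0.985), and 0 passed when adjusted over the list alone. The 1 was HBD, which fell by 0.23 ± 0.09 on average but without SKM1 it passed in the opposite direction (0.21, adjusted p = 0.00698). Of 16 reference genes 0 rose and 7 fell (mean -0.06, adjusted p = 0.102), HPRT1 by 0.29 ± 0.02, TBP by 0.27 ± 0.03, SDHA by 0.14 ± 0.03 and IPO8 by 0.10 ± 0.03. In all, camera called 17 of the 26 lists, 14 up and 3 down, and fry called these and the 6 named above. With an estimated correlation 12 held, all but the sensing, MHC class II, megakaryocyte, mitosis and BCL2 lists. With lines as the units 13 held, all but the germ-cell, sensing, megakaryocyte and mitosis lists. For the average, counts adjusted over the list alone equalled those over all genes wherever no second count is given.

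**Figure D1:**
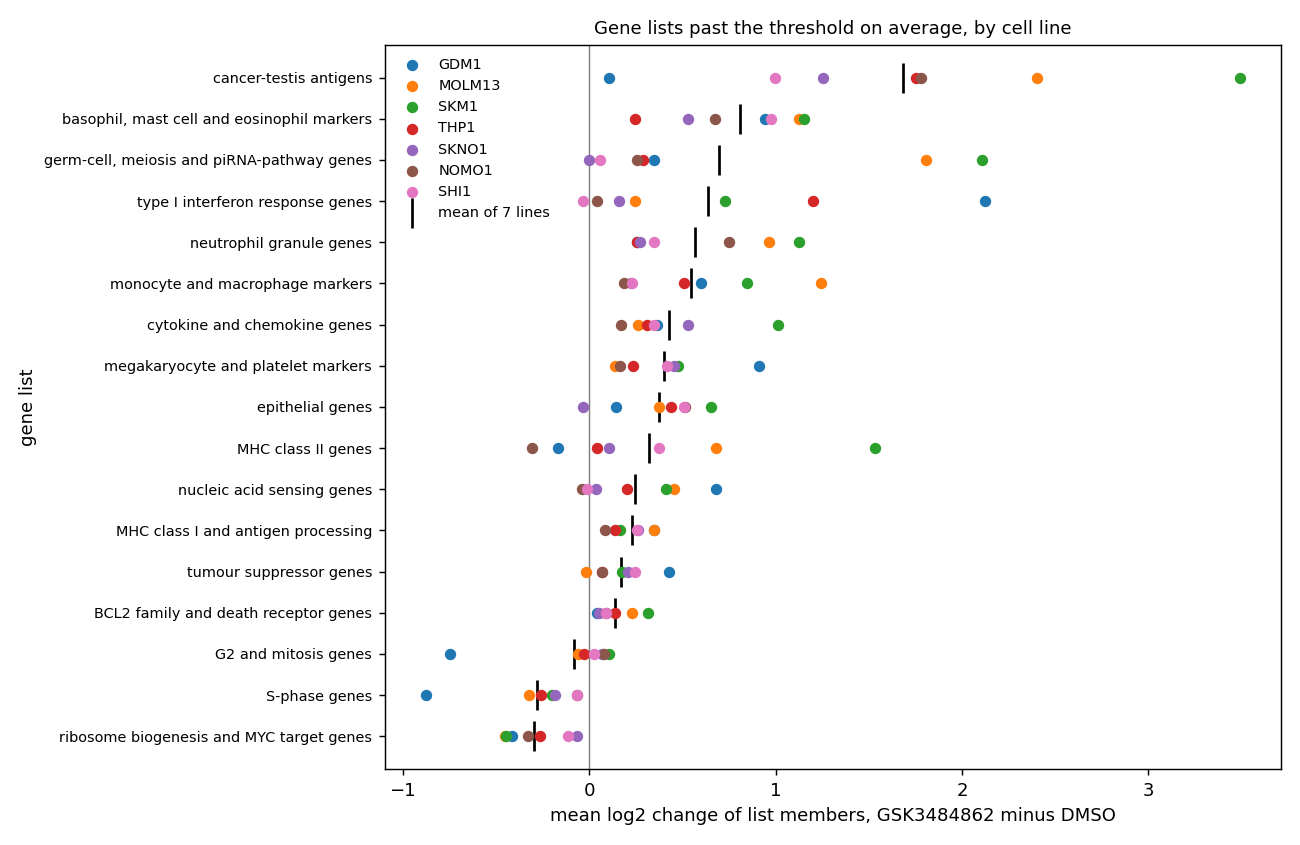
Mean log2 change, GSK3484862 minus DMSO, of the members of each of the 17 gene lists called on average (vertical axis), with 1 coloured point per cell line and a black bar at the mean of the 7 lines. The interferon list reached 2.12 in GDM1 and -0.03 in SHI1, and the S-phase list -0.88 in GDM1.

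Within single lines the comparison asked what the inhibitor changed in each. In GDM1 the monocyte calprotectin gene S100A8 rose by 8.24 ± 0.39, from a DMSO signal at the floor (2.1) to 10.37 ± 1.38 (SD, n = 2), the GTPase gene RAB13 rose by 6.56 ± 0.23 and COL14A1 by 6.38 ± 0.35. The chemokine receptor gene ACKR3 fell by 4.58 ± 0.31 and the homeobox gene IRX3 by 3.47 ± 0.10. The interferon list rose with 40 of 46 members up (mean 2.12), while 36 of 39 S-phase genes fell (mean -0.88) and 41 of 42 G2 and mitosis genes fell (mean -0.75), calls that were lost with an estimated correlation (adjusted p = 0.0506, 0.0506 and 0.0548). In total 1552 genes rose and 2388 fell in GDM1, of which 374 and 310 at 2-fold or more. GDM1 fitted on its own 4 arrays gave 2349 genes against 3940.

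In MOLM13 ZNF595, a zinc finger gene, rose by 9.22 ± 0.28, from 2.31 ± 0.11 (SD, n = 2) to 11.53 ± 0.41 (SD, n = 2). GTSF1 rose by 8.44 ± 0.11 and MAGEB2 by 7.39 ± 0.21, and the gap junction gene GJA1 fell by 4.43 ± 0.26 and the actin-binding protein gene NEXN by 3.25 ± 0.32. Monocyte markers rose with 12 of 29 members up (mean 1.24) and neutrophil granule genes with 10 of 20 up (mean 0.96), and ribosome biogenesis and MYC target genes fell with 25 of 32 down (mean -0.45), but none of the 3 held with an estimated correlation (adjusted p = 0.0632, 0.0785 and 0.0548). In total 1596 genes rose and 1798 fell, of which 532 and 139 at 2-fold or more. MOLM13 on its own arrays gave 2056 genes against 3394, and with 1 array of the series left out between 2120, without replicate 1 of treated MOLM13, and 3582.

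In SKM1 MAGEA4 rose by 8.29 ± 0.33, ZNF595 by 7.93 ± 0.28 and GTSF1 by 7.78 ± 0.11, while TBC1D30 fell by 4.24 ± 0.47 and SHISA2 fell by 4.11 ± 0.29. Cancer-testis antigens rose with 5 of 6 members up (mean 3.49), MHC class II genes with 10 of 14 up (mean 1.53) and cytokine genes with 11 of 24 up (mean 1.02), and 25 of 32 ribosome biogenesis genes fell (mean -0.45). With an estimated correlation none of the 4 calls held (adjusted p = 0.0506, 0.181, 0.0601 and 0.0548). In total 1643 genes rose and 1640 fell, of which 537 and 172 at 2-fold or more. The SKM1 duplicates had the widest spread of the 7 lines (SD 0.289 in DMSO and 0.305 after treatment), and with arrays weighted by their spread SKM1 had 1372 genes against 3283. On its own arrays SKM1 gave 53 genes, with 2570 at an unadjusted p under 0.05, and TBC1D30 and SHISA2 did not pass (adjusted p = 0.171 and 0.123).

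In THP1 MAGEA4 rose by 8.63 ± 0.33, ZNF595 by 5.81 ± 0.28 and DCAF4L1 by 5.55 ± 0.52, and the amino acid transporter gene SLC16A10 fell by 2.65 ± 0.10 and BEND7 by 2.48 ± 0.26. Of 46 interferon response genes 29 rose and 0 fell (mean 1.2), and 14 of 39 S-phase genes and 15 of 32 ribosome biogenesis genes fell (means -0.26 and -0.26), all 3 lost with an estimated correlation (adjusted p = 0.0548, 0.134 and 0.0785). In total 630 genes rose and 969 fell in THP1, of which 194 and 79 at 2-fold or more. On its own arrays limma called 2 genes in THP1 (3616 at an unadjusted p under 0.05), neither of them among the 5 named in this paragraph, with array weights 2592 against 1599, and with 1 array left out between 747, without replicate 1 of DMSO-treated THP1, and 1858.

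In SKNO1 COL14A1 rose by 8.48 ± 0.35, the scavenger receptor gene CD163L1 by 6.07 ± 0.27 and the kinase gene MAP3K13 by 5.69 ± 0.16, while the neurexin gene NRXN2 fell by 2.78 ± 0.18 and the telomerase gene TERT by 2.71 ± 0.33. Cancer-testis antigens rose with 2 of 6 members up (mean 1.26) and cytokine genes with 4 of 24 up (mean 0.53), both lost with an estimated correlation (adjusted p = 0.0785 and 0.0785). In total 346 genes rose and 364 fell, or 48.7% rises, against 60.7% with every array centred on its median, and 142 and 60 at 2-fold or more. On its own arrays limma called 0 genes in SKNO1 (2312 at an unadjusted p under 0.05), and with 1 array left out between 368, without replicate 1 of DMSO-treated SKNO1, and 827 against 710.

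In NOMO1 ZNF595 rose by 6.85 ± 0.28, NAV3 by 6.70 ± 0.21 and the transketolase-like gene TKTL1 by 5.03 ± 0.32, and FJX1 fell by 3.63 ± 0.39 and SRPX by 3.19 ± 0.42. Neutrophil granule genes rose with 7 of 20 members up (mean 0.75), and 17 of 32 ribosome biogenesis genes fell (mean -0.33), both lost with an estimated correlation (adjusted p = 0.0548 and 0.0548). In total 491 genes rose and 882 fell, or 35.8% rises, against 51.1% after median centring, and 161 and 96 at 2-fold or more. On its own arrays limma called 0 genes in NOMO1 (2523 at an unadjusted p under 0.05), and with 1 array left out between 605, without replicate 2 of DMSO-treated NOMO1, and 1554 against 1373.

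In SHI1 ZNF595 rose by 6.11 ± 0.28, MAGEB2 by 5.05 ± 0.21 and CPXM1 by 4.75 ± 0.17, and AK4 fell by 2.56 ± 0.35 (3 of its 4 probe sets with that sign) and the protein kinase A subunit gene PRKAR2B by 2.22 ± 0.18. Basophil, mast cell and eosinophil markers rose with 5 of 12 members up (mean 0.97) and MHC class I genes with 4 of 20 up (mean 0.26), both lost with an estimated correlation (adjusted p = 0.0734 and 0.0611). In total 294 genes rose and 105 fell, or 73.7% rises, against 60% after median centring, and 110 and 31 at 2-fold or more. On its own arrays limma called 0 genes in SHI1 (2656 at an unadjusted p under 0.05), with array weights 1131 against 399, and with 1 array left out between 196, without replicate 2 of DMSO-treated SHI1, and 470.

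**Figure D2:**
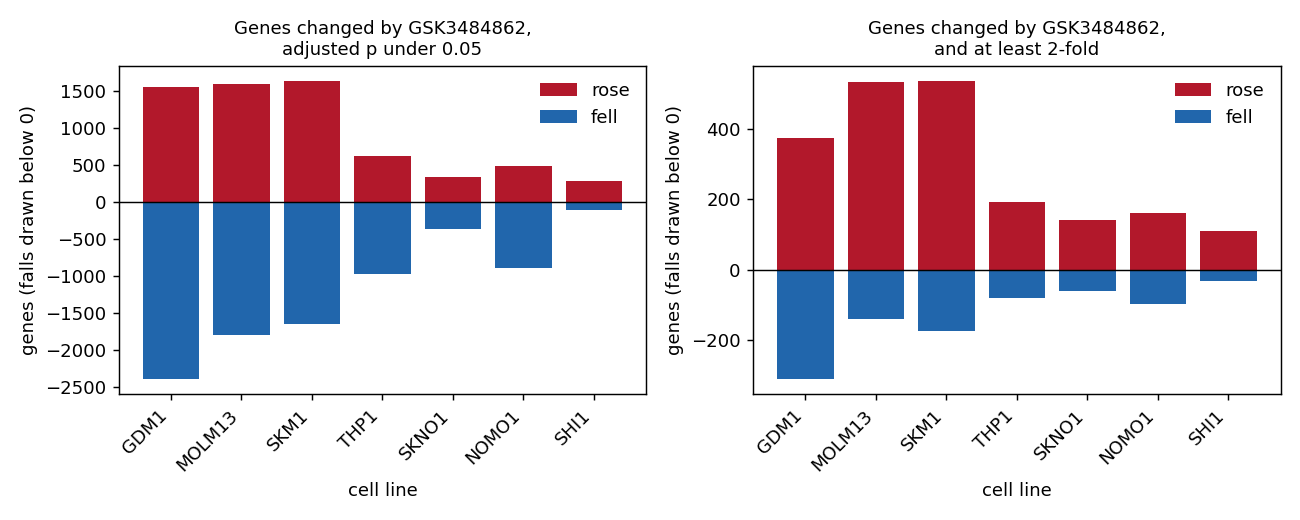
Number of genes called up (red, above 0) and down (blue, drawn below 0) per cell line at an adjusted p under 0.05, left, and at 2-fold or more in addition, right. GDM1 had 1552 rises and 2388 falls and SHI1 294 and 105; at 2-fold or more rises exceeded falls in each line, from 374 against 310 in GDM1 to 532 against 139 in MOLM13.

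The gene lists were also tested within each line. Of 182 tests of a list in a line 65 passed, 49 up and 16 down, and with an estimated correlation 0 passed, the smallest adjusted p being 0.0506. Ribosome biogenesis and MYC target genes had a lower mean in all 7 lines, from -0.45 in MOLM13 to -0.07 in SKNO1, and cancer-testis antigens a higher one, from 0.11 in GDM1 to 3.49 in SKM1.

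A further comparison asked where the response differed between lines. GTSF1 differed most clearly: its signal in DMSO was near the floor in MOLM13 (2.30) and SKM1 (2.18), where it rose by 8.44 and 7.78, while it fell by 0.33 in GDM1. In the other lines its DMSO arrays already lay between 12.7 (SHI1) and 13.3 (SKNO1). That was above the 9.93 to 10.8 of treated SKM1 and MOLM13. NAV3 ranged from 0.00 in SKNO1 to 7.13 in MOLM13, the leukotriene synthesis gene ALOX5 from -0.08 in GDM1 to 6.67 in MOLM13 and the adaptor gene DOK3 from -0.22 in SKNO1 to 4.69 in MOLM13. MLPH peaked in SHI1 (3.88) and PLBD1 in NOMO1 (1.90), the 1 line where it was called. The moderated F-test of limma found 4378 genes (37.5%) whose change differed between lines. Of 144 named genes, some of them chosen for that F-test or for their change in 1 line, 125 differed, including MAGEB2 (0.37 in GDM1, 7.39 in MOLM13) and S100P (0.30 in SHI1, 7.28 in MOLM13), while RPGRIP1L did not pass (adjusted p = 0.574).

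Among lists, each line was set against the mean of the other 6 lines, a test of the difference that was chosen after the data were seen. The interferon list moved by 1.73 more in GDM1 than in the others (adjusted p = 9.24e-27), S-phase genes by -0.70 (adjusted p = 3.25e-23) and G2 and mitosis genes by -0.78 (adjusted p = 5.58e-27). MHC class II genes moved by 1.41 more in SKM1 (adjusted p = 1.77e-05), cancer-testis antigens by 2.11 more in SKM1 (adjusted p = 1.73e-06) and by -1.84 in GDM1 (adjusted p = 4.45e-04), and monocyte markers by 0.81 more in MOLM13 (adjusted p = 0.00358). Of 182 such tests 40 passed, and with an estimated correlation 0 did, the smallest adjusted p being 0.0554.

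**Figure D3:**
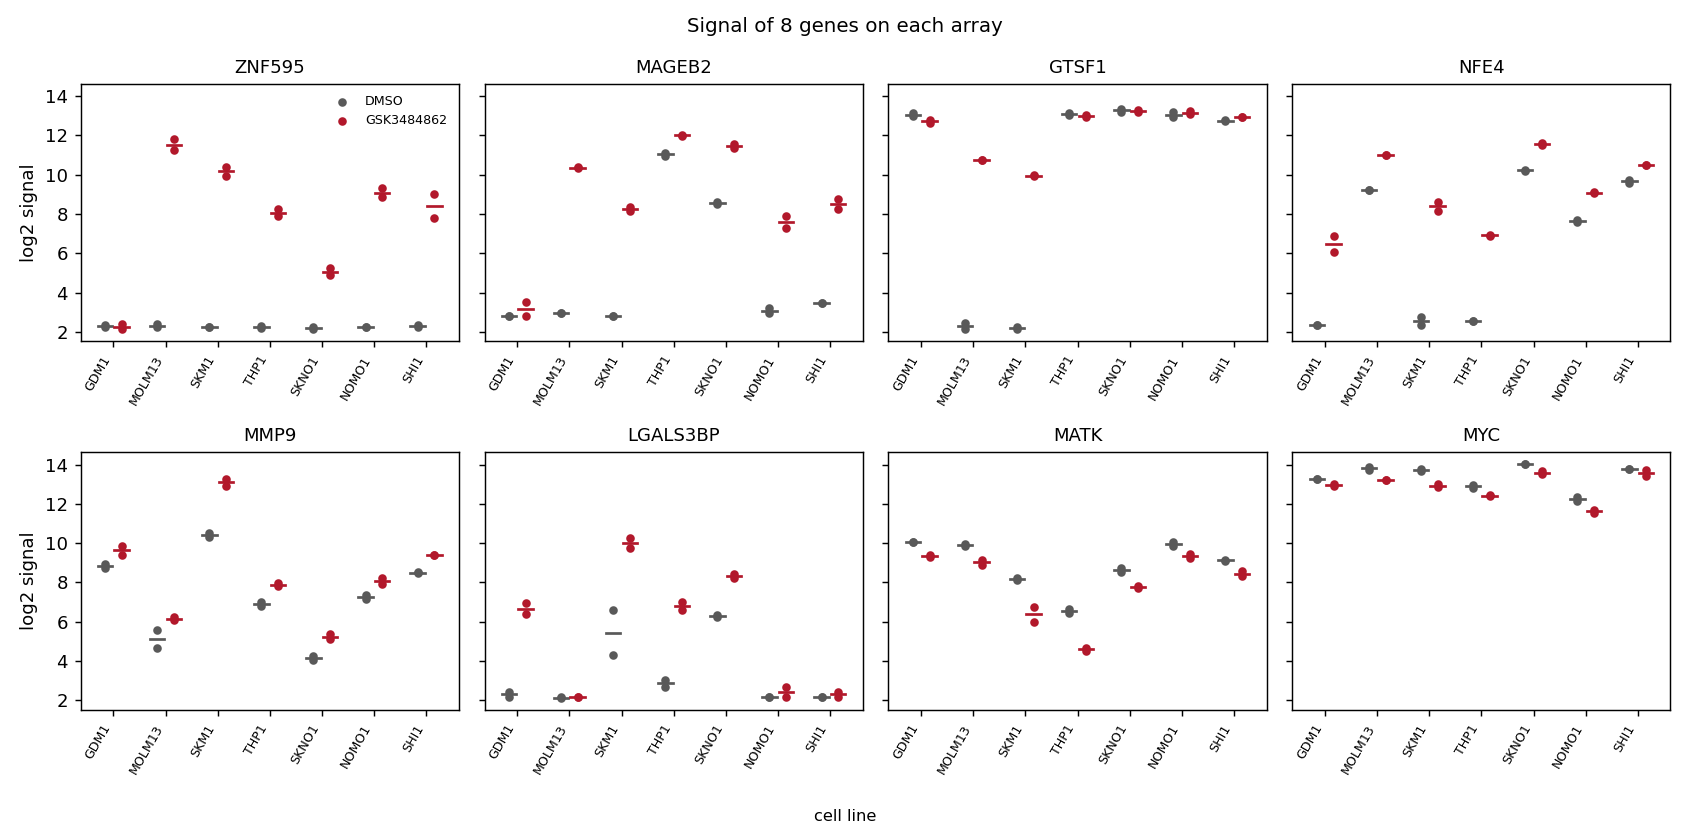
Log2 signal (vertical axis) of 8 genes on each of the 28 arrays, by cell line (horizontal axis), with DMSO in grey, GSK3484862 in red, 1 point per array and a bar at the mean of each pair of duplicates. ZNF595 was near the floor in every DMSO array and rose in 6 lines but not in GDM1. GTSF1 rose in MOLM13 and SKM1 and was already high in DMSO in the other lines. MATK was lower after treatment in all 7 lines.

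The last comparison asked how far the lines shared their responses. ZNF595 and MAGEB2 were called up in 6 lines, with averages of 5.54 ± 0.11 and 3.81 ± 0.08, as were S100P, ADORA3 and the lymphocyte surface gene CD52 (1.76 ± 0.04). The 4 genes called down in all 7 lines were MATK, RNASEH1-DT, the methyltransferase gene SMYD2 (-0.54 ± 0.03) and the pseudouridine synthase gene PUS7 (-0.48 ± 0.02). ZNF595, CD52, SMYD2 and PUS7 were named here after their values were seen. In at least 5 lines 104 genes rose and 213 fell, against 0.35 and 0.88 if calls in the lines were independent. For each of the 21 pairs of lines, which share no control arrays, the genes called in the same direction outnumbered n1 × n2 / N, for example 643 rises in MOLM13 and SKM1 against 225. That pair also shared 867 falls, and 78 genes were called in opposite directions. All lines share 1 estimate of the spread of each gene, which makes calls coincide, so neither reference is a chance level. Across genes, which are not independent replicates, the changes of pairs of lines correlated at r = 0.167 (GDM1 and NOMO1) to 0.416 (MOLM13 and SKM1), with a median of 0.313. The lines were not more alike after treatment: the mean correlation of expression between lines was 0.839 in DMSO and 0.834 after treatment, higher after treatment in 7 of 21 pairs. Every pair with GDM1 was lower after treatment, with differences from -0.0197 (MOLM13) to -0.0118 (THP1). Pairs without GDM1 went both ways, from -0.0077 (THP1 and NOMO1) to 0.0122 (SKM1 and NOMO1).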

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

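Chosen only after the result was seen were the test of each list in 1 line against the other 6 lines and the tests of genes bright or dim in a line. The response differed between lines for 4378 genes (37.5%) by the moderated F-test of the difference itself, and for 125 of 144 named genes, some of which were chosen for that F-test or for their change in 1 line. Over the 7 lines the log2 change spanned 8.76 for GTSF1, 7.13 for NAV3, 6.74 for ALOX5, 4.92 for DOK3, 4.05 for MLPH and 1.96 for PLBD1. Among lists 40 of 182 differences of a line from the other 6 lines passed, 0 of them with an estimated correlation, where the smallest adjusted p was 0.0554. Those with the smallest p were G2 and mitosis genes in GDM1 (-0.780), the interferon list in GDM1 (1.73), SHI1 (-0.783) and NOMO1 (-0.697), and S-phase genes in GDM1 (-0.696) and NOMO1 (0.252). Cancer-testis antigens in SKM1 (2.11) and GDM1 (-1.84) differed by more, with larger p. Among 4726 probe sets with no or several gene symbols, which the comparisons left out, 1410 passed on average, 724 up and 686 down, and 25 rose at least 2-fold against 0 that fell as far. The strongest 3 rose by 4.92 ± 0.14 (higher in 7 of 7 lines), 2.40 ± 0.05 (higher in 6) and 2.34 ± 0.08 (higher in 6).

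The number of genes called ran from 399 in SHI1 to 3940 in GDM1. With array weights the count in SHI1 was higher, as given below, so the width of this range depends on how precision is weighted. Unequal precision of the duplicates was argued against as the whole cause, since the size of change shared by both replicates, which noise does not raise, was 1.96 ± 0.101 (SE) times as large in GDM1 as in SHI1. The counts did not rank the lines by that shared change. It was larger in SKM1 (0.603) and MOLM13 (0.584) than in GDM1 (0.542), which had more calls. The level of the DNMT1 transcript in DMSO stayed open: with that shared change it gave r = -0.149 (exact permutation p = 0.794, adjusted 0.794) and rho = 0.0714 (exact permutation p = 0.906) over 7 lines, and r = 0.571 without SHI1 and SKNO1, so the sign rested on those lines. Slower proliferation, read from the S-phase list, also stayed open, with r = -0.519 (exact permutation p = 0.214, adjusted 0.514 over 3 relations), rho = -0.714 (exact permutation p = 0.0881) and r = -0.518 without GDM1 and SHI1. Doubling times, which could decide whether lines that divide more lose more methylation in 96 hours, were not used here.

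Summed over lines, 2050 rises and 887 falls reached 2-fold (69.8% rises). Scaling of the arrays was argued against, as 68.4% were rises after quantile normalization. The floor of the scale, which leaves dim genes no room to fall, stayed open as a cause. Among genes whose mean in the line itself lay above the median of all values 73.9% were rises, with a jackknife error over lines of 10.8. Their share was 53.6% in GDM1, where all genes gave 54.7%. In the other lines it ran from 75.8% in SKNO1 to 89.5% in NOMO1, on as few as 13 rises and 2 falls in SHI1. Those lines argue against the floor as the cause among their bright genes, while GDM1 decides nothing. Among the genes not above that median 68.3% were rises (error 4.37), which the floor and real rises could both give. Release of silenced genes was not tested, since DNA methylation was not measured here.

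The interferon list had a mean change of 2.12 in GDM1 and of -0.03 to 0.16 in NOMO1, SHI1 and SKNO1; with an estimated correlation neither the rise in GDM1 (adjusted p = 0.0506) nor its difference from the other lines (adjusted p = 0.0554) passed. A level before treatment near that of treated GDM1 was argued against in those lines. Treated GDM1 exceeded their DMSO levels by at least 1.94 ± 0.415 (SE over members, in SHI1), and by 3.15 in NOMO1 and 3.14 in SKNO1. A limit below the level of treated GDM1 stayed open for SHI1. Its DMSO mean of 8.23 was the highest of the 7 lines and lay above treated SKM1 (7.52), though GDM1 itself rose from 8.04. A few extreme probe sets in GDM1 were argued against as well, since 87.0% of members were called up there, with a median change of 1.89. The level of nucleic acid sensing genes before treatment may matter but stayed open, with r = -0.426 (exact permutation p = 0.342, adjusted 0.514), rho = -0.607 (exact permutation p = 0.167) and r = 0.112 without NOMO1 and SHI1, so the relation rested on those lines.

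Chance was tested by exchanging labels within lines. A split could keep the real or the fully exchanged labels in single lines. The counts of the other splits can thus hold part of the treatment effect and are not a level without it. Of 100 such splits 1, the real one, gave as many as 6039 genes on average, the highest other giving 3922 and the median of the others 29. Likewise 1 gave as many as 17 lists, the median of the others being 6. The highest other gave 16 lists, as 3 splits did, 1 of them with only 69 genes called. A share of 1 in 100 is the smallest that 100 splits can give, so chance was argued against for the genes but not excluded. For the number of lists the margin was 1 list, which argues only weakly against chance.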

How the results depend on the processing

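Chosen only after the data were seen were the fit without SKM1 for single lines and the test of each line against the other 6. Of 162 named gene results and 26 lists under 52 settings, 6869 gene values and 1228 list values kept direction and side of the threshold, 374 and 19 lost the threshold, 4 and 15 gained it, and 6 and 12 changed sign. For what did not keep its side, the cause was not tested unless a reason is given. The floor at 2.1 limits the size of changes in dim genes.

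With array weights SKM1 had 1372 genes, THP1 2592 and SHI1 1131, with weights from 0.404 (SKM1 DMSO) to 1.70 (SHI1 DMSO). On their own 4 arrays, with 2 residual degrees of freedom, limma called 2349 genes in GDM1, 2056 in MOLM13, 53 in SKM1, 2 in THP1, 0 in SKNO1, 0 in NOMO1 and 0 in SHI1 (unadjusted p under 0.05: 4606, 4539, 2570, 3616, 2312, 2523 and 2656). With lines as units 825 genes passed on average. At least 2-fold were 167 genes on average, 684 in GDM1, 671 in MOLM13, 709 in SKM1, 273 in THP1, 202 in SKNO1, 257 in NOMO1 and 141 in SHI1, with 23 shared by at least 5 lines. At an adjusted p under 0.01 stood 2092 in MOLM13, 2068 in SKM1, 717 in THP1, 333 in SKNO1, 597 in NOMO1, 184 in SHI1, 2455 differing between lines and 82 shared. Within lines camera with an estimated correlation called 0 lists, against 65 with the preset one.

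With 1 array left out, its partner being assumed to vary like the other groups, or 1 replicate of every group, counts ran from 0 to 6126 on average, 2120 to 3582 in MOLM13, 747 to 1858 in THP1, 368 to 827 in SKNO1, 605 to 1554 in NOMO1, 196 to 470 in SHI1 and 194 to 354 for sharing, and stayed within 1.5 times in GDM1 (2754 to 4129) and SKM1 (2650 to 3343). The 0 came from limma without replicate 1 and also without replicate 2 (unadjusted 2954 and 3171), where the spread between lines is the error. Counts moved by over 1.5 times in MOLM13 without DMSO 1 (2132) or treated 1 (2120); in THP1 without DMSO 1 (747) or 2 (903) or treated 1 (849) or 2 (817); in SKNO1 without DMSO 1 (368) or 2 (457) or treated 2 (429); in NOMO1 without DMSO 2 (605) or treated 1 (630) or 2 (790); in SHI1 without DMSO 1 (228) or 2 (196) or treated 1 (212); and for sharing without THP1 DMSO 1 (205) or 2 (210), THP1 treated 2 (194) or NOMO1 treated 1 (209).

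Signs changed as follows, HBD passing in both directions. The unfolded protein list moved to 0.000923 with quantile normalization, 0.000504 with the filter on dim probe sets, 0.0298 without GDM1, and with arrays left out to 0.00198 (GDM1 DMSO 1), 0.00781 (SKM1 DMSO 2), 0.00753 (SKM1 treated 1) and 0.00116 (replicate 1), from a lowest -0.0229 (SKM1 DMSO 1). The erythroid list moved to 0.0510 with the filter, 0.0958 without SKM1, 0.00594 without GDM1 treated 1 and 0.00100 without replicate 1, from a lowest -0.0446 (GDM1 treated 2). Without GDM1 the G2 and mitosis list was at 0.0312 and UHRF1 at 0.0281. DNMT3A was at 0.0142 without MOLM13, 0.00359 without THP1 and 0.00905 without SKNO1, HBD at 0.207 (adjusted p = 0.00698) and DNMT3B at -0.000184 without SKM1. DNMT3A passed without SKM1 (-0.17) and GDM1 (-0.14), DNMT3B without GDM1 (0.15) and without SKNO1 treated 1 (adjusted p = 0.0466). The cholesterol list passed without NOMO1 (adjusted p = 0.0387), SHI1 (0.0323), SKM1 DMSO 1 (0.0255), SKM1 treated 2 (0.0382), THP1 DMSO 1 (0.0431) or replicate 1 (0.0326), and the reference list without SKM1 DMSO 1 (0.0488).

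With replicate numbers as a paired replicate block, 6210 genes passed on average by pairs within lines and 6060 by number over all lines, each with 18 lists, the cholesterol list being added (adjusted p = 0.0235 and 0.0496). By pairs GDM1 had 4036 genes, MOLM13 3459, SKM1 3487, THP1 1756, SKNO1 780, NOMO1 1405 and SHI1 462, with 4342 differing between lines, and HBD lost the threshold (adjusted p = 0.0831). Deviations of like-numbered arrays correlated above 0.1 in 3 of 7 lines, SKM1 (0.372), SKNO1 (0.391) and NOMO1 (0.309), against a median of 0.0135 between lines. As this held in 3 lines only, the numbers were not taken as pairs in the main fit, and pairing stays open in those 3.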

Other observations

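The limits that define a switched gene were chosen only after the data were seen. Genes with both DMSO arrays at or below 4 and both treated arrays at or above 7 numbered 9 in GDM1, 20 in MOLM13, 21 in SKM1, 3 in THP1, 6 in SKNO1, 5 in NOMO1 and 3 in SHI1, or 67 events, against 1 event in the opposite direction, in MOLM13. These were 52 genes, 9 of them in at least 2 lines and 3 in at least 3: ZNF595 in 5 lines, MAGEB2 in 4 and NAV3 in 3. The other 6 were COL14A1, CPXM1, DCAF4L1, GTSF1, MAGEA4 and OLFML3.

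Since ZNF595 and the X-linked MAGEB2 and MAGEA4 were among the largest rises, it was asked whether their classes rose as a whole. Zinc finger (ZNF) genes might rise as a family, but their 391 members had a mean change of 0.0568 (adjusted p = 0.159, and adjusted p = 0.518 with an estimated correlation), and 0.767% of them rose at least 2-fold against 1.38% of all genes. X-linked genes gave a mean of 0.0577 over 376 genes (adjusted p = 0.159, and adjusted p = 0.518 with an estimated correlation), with 2.1% rising at least 2-fold. Long non-coding RNA genes gave a mean of 0.0771 over 512 genes (adjusted p = 0.0546, and adjusted p = 0.227 with an estimated correlation), with 1.95% rising at least 2-fold. None of the 3 classes passed, which leaves a small shift of each open.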
